A study of Homo sapiens with 2 samples.

How the data were processed

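The samples were 2 arrays of 1 group, each with DNA recovered by an antibody to TEL from REH cells in the Cy5 channel and input DNA in the Cy3 channel, per the labels. Per the labels' protocols, chromatin was crosslinked and sheared, and DNA was amplified by ligation-mediated PCR before labelling. Per the file headers, NimbleScan 2.4.27 extracted 1 intensity per probe and channel from each scanned image, for a tiling design on build hg18. The deposited intensity values showed no background subtraction, since none was below 0 and random-sequence probes were well above 0. The mismatch column held only zeros and was not used.

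The value table of the series holds the authors' processed log2 values of the same arrays, whose normalization is not given in the sources used here. Its direction and scale were set against the scanner values. In 23 tiles with loess ratios of at least 1 in size in each array, the table had the same sign in all 23, with slopes of 0.95 and 0.81 on the loess ratios, so the values were read as log2 of ChIP over input. Their correlation with loess ratios was 0.39 and 0.33, and 0.77 and 0.79 with a running median of those over 7 probes, so the values appear smoothed along the genome. The median of each column was 0.04. The exact centring and smoothing stay unknown. Random-sequence probes are not among the probes of this table used here.

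In the main setting, the log2 ratio of Cy5 over Cy3 of each probe was centred on the median over the genomic probes of its array, which had been -1.59 and -1.94. No loess was used in the main setting, since many probes of a ChIP array can shift one way. Ratios were averaged over non-overlapping tiles of 500 bp with at least 3 probes and over tiled regions with at least 5 probes. Tiles and regions were tested against 0 with limma 3.58.1 (intercept only, eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. With 2 arrays there was 1 residual degree of freedom, so the variance shared over tiles carries the test, and the number of arrays limits the precision. A rule of size counted tiles with a ratio of at least 1, or at most -1, in each array. Clusters were called in each array alone from probe-centred windows of 500 bp with at least 4 probes. Their cutoff was the lowest at which 20 permutations of values over positions gave at most 5% of the observed windows. Tables were handled with the data.table package (1.17.8) and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

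The tile test was tested on simulated data with the estimated spread of the 53412 tiles. It recovered 97 of 100 tiles changed by 1 and 11 of 100 changed by 0.5, with 11 false calls. The simulated tiles were independent and held no brightness trend or shared probe effects. The 11 false calls are therefore not an error rate for the real arrays. Cluster calling on permuted ratios of array 1 recovered 49 of 50 implanted stretches, with 11 further clusters.

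The alternatives fixed before the data were examined were normexp with an offset of 50, Tukey biweight centring, within-array loess (lowess, span 0.3, genomic probes only, then centred), the centred value table, medians over probes, leaving out probes among the dimmest 10% of the input channel in either array (66471 probes), leaving out 898 probes that occur more than once, other tile widths and minimums, a stricter threshold, limma treat at 0.5, other size rules, other cluster settings and each array alone. Alternatives chosen after seeing the data were the ratio relative to a lowess curve of random-sequence probes, loess over all probes without centring, and the value table without centring.

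The text names regions and tiles by a rule fixed before the data were examined: the miRNAs in the study's title, the 10 highest called regions with both arrays above 0, the 6 lowest called regions with both arrays below 0, and the 10 highest called tiles. Any other region, tile, transcript, cluster or stretch was named after its values were seen, whether or not the text repeats it. Lists of miRNAs fixed in advance were not tested, because the files give regions by hg18 position without miRNA names and the gene table used here (GRCh38) served for names only. Of 12 housekeeping accessions, 11 matched that table. A correction for GC content was not run, since no genome of the build was used here.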

Results

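The data came from chromatin immunoprecipitation on tiling arrays (ChIP-chip) in REH cells, a human B-cell precursor leukaemia line that carries the TEL-AML1 (ETV6-RUNX1) fusion. Chromatin was pulled down with an antibody to TEL, and the recovered DNA (Cy5) was hybridised together with input DNA (Cy3) on a 2-colour array. There were 2 arrays in 1 group, and each array compared ChIP DNA with input DNA. No mock or IgG pull-down was analysed here. Counts of tiles below 0 are given beside those above, with 0 set by median centring of each array. The labels do not say that the arrays came from separate cultures. The p-values therefore measure the spread between these 2 arrays only, which may be technical.

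Each array held 385284 probes, of which 375284 were genomic and 10000 had random sequences with no intended target. The genomic probes tiled 297 miRNA regions (120422 probes), 150 snoRNA regions (58913 probes), 83 piRNA regions (55846 probes), 14 ENCODE regions (139744 probes) and 12 housekeeping transcripts (359 probes). The median miRNA region spanned 24945 bp with 406 probes. In array 1 the median genomic probe had a brightness of 366 in the ChIP channel and 1108 in the input channel. In array 2 the medians were 323.67 and 1328. Only 11.5% of genomic probes in array 1 and 10.3% in array 2 exceeded the 95th percentile of the random-sequence probes in the ChIP channel. In the input channel the shares were 12.8% and 10.2%.

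The log2 ratio of ChIP over input followed probe brightness in both arrays. Its correlation with mean log2 brightness across genomic probes was 0.75 in array 1 and 0.78 in array 2. The random-sequence probes had correlations of 0.77 in each array. Probes are not independent replicates, and these values describe each array. After centring, the dimmest 20% of genomic probes had a median ratio of -0.80 in array 1 and -0.66 in array 2, and the brightest 20% had medians of 1.30 and 1.44.

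**Figure D1:**
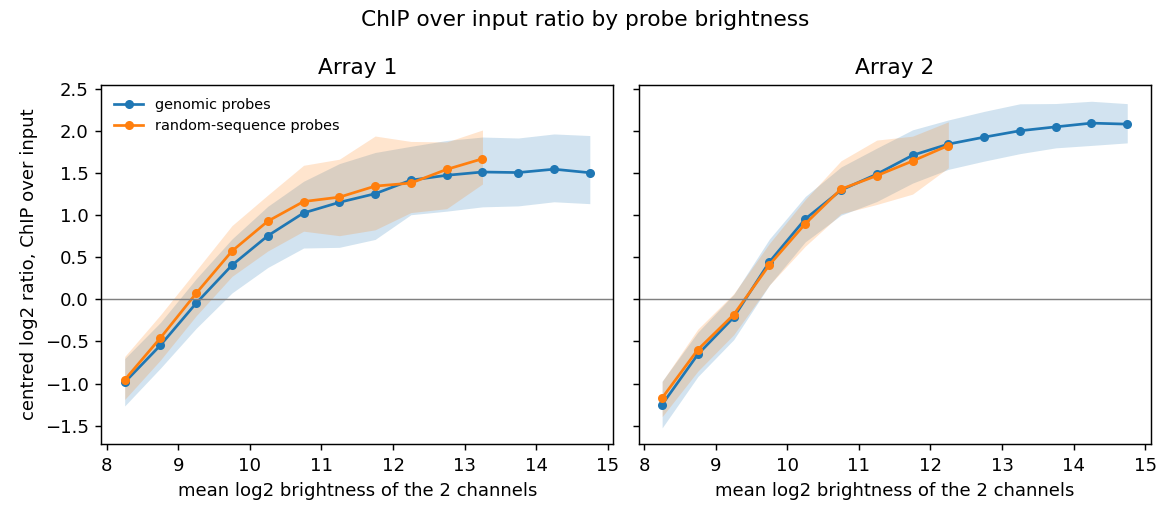
Centred log2 ratio of ChIP over input (vertical axis) against mean log2 brightness of both channels (horizontal axis) in each array, with points at the median and shading from the 25th to the 75th percentile for genomic and random-sequence probes (bins with at least 50 probes). Both kinds of probe climb with brightness. At 12.25 the genomic and random-sequence medians are 1.41 and 1.38 in array 1, and 1.84 and 1.82 in array 2. At 9.75 they are 0.41 and 0.57 in array 1, and 0.44 and 0.41 in array 2. In array 1 the random-sequence median is the higher in all bins shown for both kinds except that at 12.25.

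The first comparison asked where DNA recovered with the TEL antibody exceeded input DNA. Of 53412 tiles of 500 bp, 16290 (30.5%) were called higher in the ChIP channel and 7626 (14.3%) lower (limma, Benjamini-Hochberg adjusted p under 0.05). The called-higher share was 34.6% in miRNA regions, 35.6% in piRNA regions, 27.7% in snoRNA regions and 27.5% in ENCODE regions. It was highest in housekeeping transcripts, at 45.7% (21 of 46 tiles). These counts depended on how brightness was treated. With within-array loess, 4 tiles were called higher and 33 lower, with 6041 tiles at an unadjusted p under 0.05. After normexp background correction, 612 were called higher and 1444 lower.

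The highest tile lay in an ENCODE region on chromosome 22, from 31716000 to 31716499 (hg18, positions as in the files). Its log2 ratio was 4.91 in array 1 and 3.58 in array 2, a mean of 4.24 ± 0.94 (SD, n = 2, limma adjusted p = 5.75e-08). In array 1, 1 of its 3 probes was saturated in the ChIP channel, so the array 1 ratio and the mean are lower bounds and the SD is uncertain. It stayed called with loess, at a mean of 2.66 (adjusted p = 0.017). The call also held in the value table (limma adjusted p = 0.016) and with the random-sequence curve (limma adjusted p = 0.034). An ENCODE tile on chromosome 22 from 30898000 to 30898499 had a mean of 2.12 ± 0.09 (SD, n = 2, limma adjusted p = 1.03e-06) and was also called with loess, at 0.97 (adjusted p = 0.035). This tile lost the call in the value table (0.615, limma adjusted p = 0.098) and with the random-sequence curve (0.93, limma adjusted p = 0.078). A snoRNA-region tile on chromosome 19, from 17832500 to 17832999, had ratios of 2.32 and 1.62, a mean of 1.97 ± 0.49 (SD, n = 2, limma adjusted p = 3.1e-06). Its loess mean was 1.18 (adjusted p = 0.042). The chromosome 19 tile lost the call in the value table (1.00, limma adjusted p = 0.062) and with the random-sequence curve (1.11, limma adjusted p = 0.078).

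**Figure D2:**
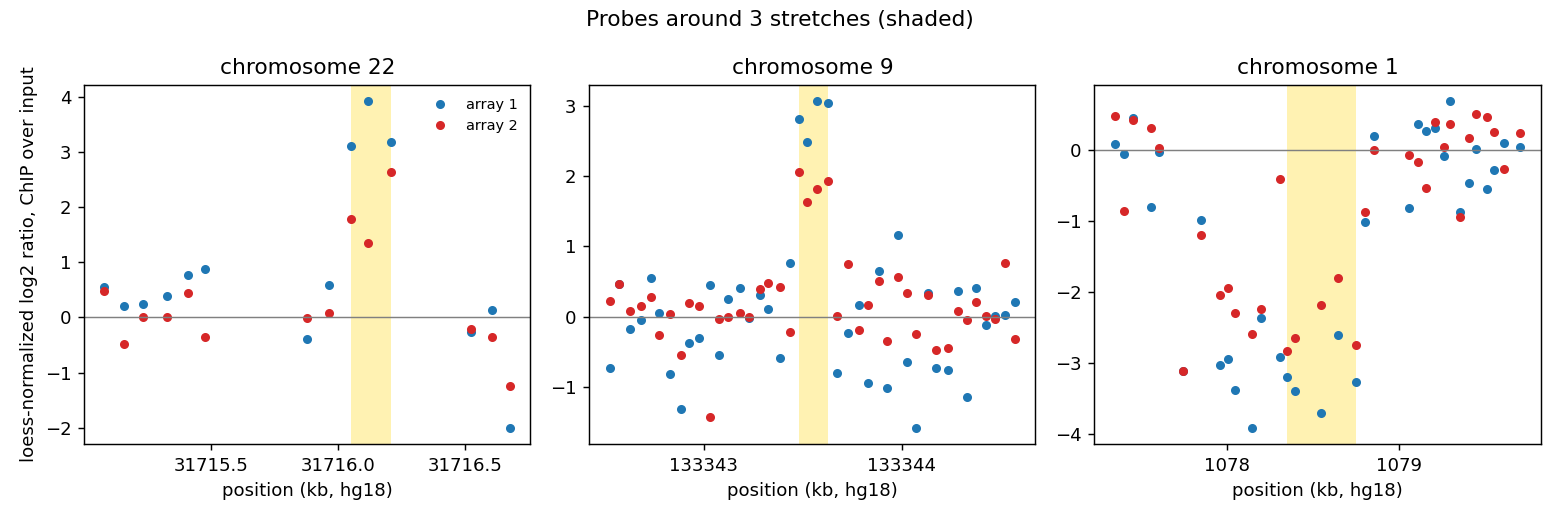
Loess-normalized log2 ratio of ChIP over input (vertical axis) of single probes against position (horizontal axis, kb, hg18) around 3 stretches (shaded) chosen after their values were seen, with blue points for array 1 and red for array 2. The chromosome 22 stretch has means of 3.40 and 1.93, the chromosome 9 stretch 2.85 and 1.86, and the chromosome 1 stretch -3.23 and -2.44.

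The other 7 of the 10 highest tiles were not called with loess. An ENCODE tile on chromosome 7 from 90143500 to 90143999 had a mean of 2.07 ± 1.31 (SD, n = 2), and loess ratios of 1.87 in array 1 and 0.14 in array 2, so array 1 carries its loess mean of 1.01. A piRNA-region tile on chromosome 17 from 18228000 to 18228499 had a mean of 2.02 and 0.73 with loess, and was called in the value table (limma, adjusted p = 0.0219). The miRNA-region tile on chromosome 7 from 158019500 to 158019999 had a mean of 1.89 and a loess mean of 0.31. ENCODE tiles on chromosome 11 from 2114500 and on chromosome X from 153370500 had means of 1.93 and 1.87, with loess means of 0.38 and 0.50. The ENCODE tiles on chromosome 22 from 31485500 and on chromosome 11 from 1910500 had means of 1.90 and 1.89, and loess means of -0.06 and -0.02. Each of these tiles held a probe saturated in the input channel of array 1, and the chromosome 22 tile also held 1 saturated in the ChIP channel of each array. The fourth tile called higher with loess lay outside this group of 10 and is named because of that call: a miRNA-region tile on chromosome 10 from 76981500, with a main mean of 1.50 and a loess mean of 0.88 (limma adjusted p = 0.042). This tile was not called in the value table (0.31, limma adjusted p = 0.34) or with the random-sequence curve (0.82, limma adjusted p = 0.12).

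A rule of size, with no test, counted tiles with a log2 ratio of at least 1 in each array. There were 879 such tiles, against 67.5 that independent arrays would give, and 2 tiles at -1 or lower in each array, against 0.51. Random-sequence probes, which have no intended target, also repeated between the arrays (r = 0.63). Arrays of the same probes are therefore not independent, and an excess over these counts does not require binding. The 879 comprised 446 in ENCODE regions, 255 in miRNA regions, 100 in piRNA regions, 76 in snoRNA regions and 2 in housekeeping transcripts. With loess, 1 tile met the upper rule and 22 met the lower rule.

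The second comparison took each tiled region as a unit, since the array was designed around non-coding RNA promoters. Of 552 regions with at least 5 probes, 318 were called higher and 92 lower. Among the 297 miRNA regions, 169 were called higher and 60 lower, with a median log2 ratio of 0.14 and a range from -0.29 to 0.86. Higher calls also covered 61 of 79 piRNA regions, 71 of 150 snoRNA regions, 9 of 14 ENCODE regions and 8 of 12 housekeeping transcripts. With medians over probes in place of means, 216 regions were called higher and 225 lower, so the excess of higher calls was lost. With loess, no region of the 552 was called higher by limma and 14 were called lower, with 27 at an unadjusted p under 0.05.

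The highest region was a housekeeping control that the gene table used here did not name, at 1.29 ± 0.22 (SD, n = 2, limma adjusted p = 5.63e-06). Its loess mean was -0.25, on the other side of 0. The loess ratios were -0.04 in array 1 and -0.46 in array 2, so array 2 carries that mean. The highest miRNA region lay on chromosome 17, from 76703671 to 76729278, at 0.86 ± 0.09 (SD, n = 2, limma adjusted p = 5.63e-06). It was followed by miRNA regions on chromosome 8 from 145081347 to 145106347 at 0.85, chromosome 20 from 61265297 to 61290297 at 0.81, chromosome 22 from 44872293 to 44898230 at 0.79, chromosome 2 from 241029091 to 241054091 at 0.79 and chromosome 9 from 138669875 to 138694875 at 0.76. The lowest ratio of these 6 in either array was 0.70. Their loess means were 0.09, 0.04, 0.04, 0.07, 0.10 and 0.07, none called. The highest tile of the chromosome 17 region, from 76726500 to 76726999, had ratios of 1.50 and 1.93.

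GAPDH, the transcript of a glycolytic enzyme, had a mean of 0.77 ± 0.17 (SD, n = 2, limma adjusted p = 1.37e-05) and a loess mean of -0.24 that was called lower (adjusted p = 0.00037). The piRNA regions on chromosome 1 from 241265600 to 241312400 and on chromosome 15 from 82630000 to 82691000 had means of 0.74 and 0.72, and loess means of -0.23 and -0.10.

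The lowest called regions had smaller ratios. The miRNA region on chromosome 8 from 100608040 to 100633040 had a mean of -0.29 ± 0.01 (SD, n = 2, limma adjusted p = 6.99e-05). The miRNA regions on chromosome 13 from 49511110 to 49536256, chromosome 21 from 16818280 to 16844019 and chromosome 18 from 17649657 to 17677963 had means of -0.27, -0.26 and -0.25. The snoRNA regions on chromosome 11 from 9391889 to 9416889 and on chromosome 1 from 210577783 to 210602783 both had means of -0.25. None of these 6 was called with loess.

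**Figure D3:**
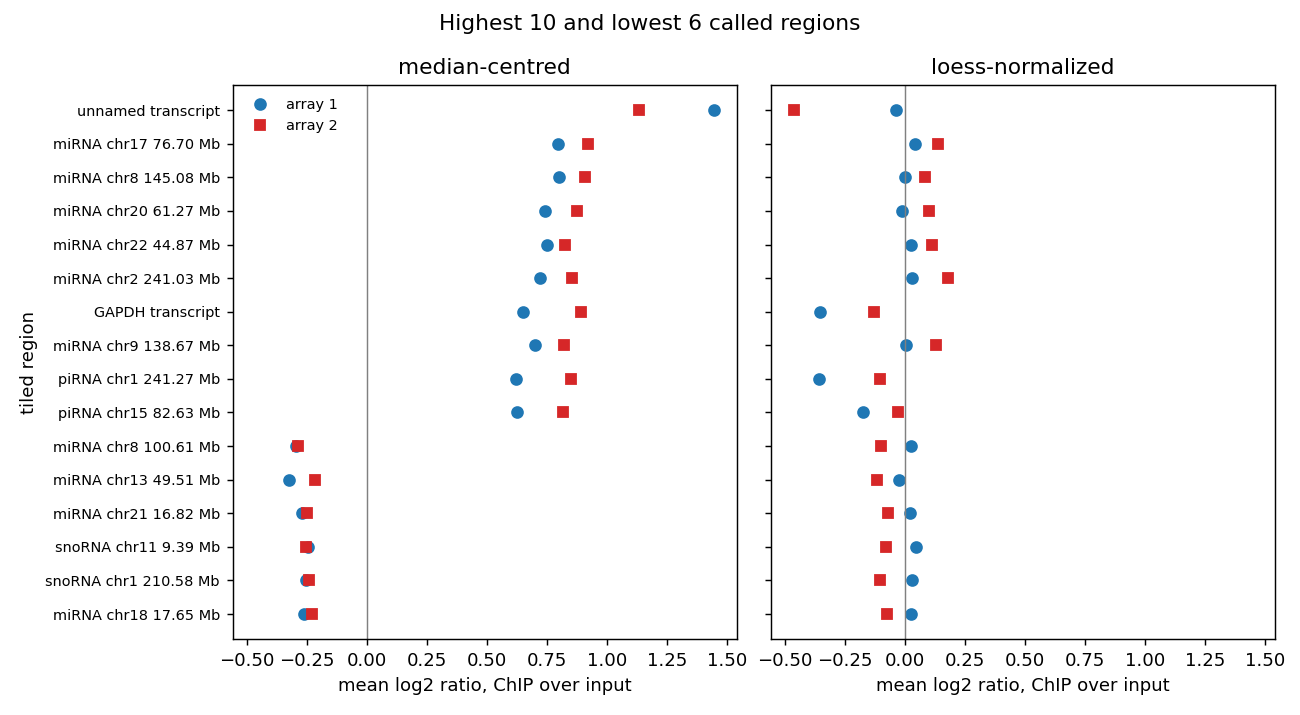
Mean log2 ratio of ChIP over input (horizontal axis) of the 10 highest and 6 lowest called regions (vertical axis, hg18 start positions), with circles for array 1 and squares for array 2, in the median-centred setting at left and after loess at right. The highest miRNA region falls from 0.86 to 0.09 and the lowest from -0.29 to -0.04 as means of both arrays.

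The study's title names miR-494 and miR-320a. The files give regions by hg18 position with no miRNA names, and the gene table used here is of another build, so the regions of these 2 miRNAs were not singled out. That table places MIR494 on chromosome 14 and MIR320A on chromosome 8. The 9 miRNA regions tiled on chromosome 14 had means from -0.10 to 0.63, of which 7 were called higher and 1 lower. The 14 miRNA regions on chromosome 8 had means from -0.29 to 0.85, of which 6 were called higher and 5 lower. With loess, the means ranged from -0.03 to 0.08 on chromosome 14 and from -0.09 to 0.04 on chromosome 8, and limma called no region and no tile among them. The main setting had 14 tiles with a ratio of at least 1 in each array among the 553 miRNA-region tiles on chromosome 14, and 13 among the 682 on chromosome 8.

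The third comparison set the arrays against each other. Across the tiles, the ratios had a Pearson r of 0.79 and a Spearman rho of 0.79. Across genomic probes r was 0.70 and rho 0.68, and across random-sequence probes r was 0.63. The log2 signals correlated with r of 0.87 in the ChIP channel and 0.80 in the input channel. With loess, r fell to 0.28 across tiles, 0.27 across genomic probes and 0.24 across random-sequence probes. Tiles and probes are not independent replicates, and no p-value was computed.

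Clusters of high windows called in each array alone numbered 13 in array 1 and 2 in array 2. Both clusters of array 2 overlapped clusters of array 1. One lay in an ENCODE region on chromosome 22, from 31715627 to 31716457 in array 1 and from 31715717 to 31716457 in array 2. The other lay in a miRNA region on chromosome 11, from 72017059 to 72017919 in array 1 and from 72017364 to 72017919 in array 2. The tile from 72017000 there, named after its values were seen, had a main mean of 1.58. It was called in the value table (1.06, limma adjusted p = 0.0022). The call was lost with loess (0.84, limma adjusted p = 0.057) and with the random-sequence curve (0.76, limma adjusted p = 0.13). Moving the clusters of array 2 at random within their regions gave a mean of 0.08 shared clusters over 100 draws, with at most 1 in any draw. Effects of single probes that repeat between arrays could also give shared clusters, so this comparison does not single out bound sites. With the sign of the ratios turned, array 1 gave 3 clusters, array 2 gave 0 and none were shared. The other array 1 clusters in miRNA regions were on chromosome 12 from 6944625 to 6945125, chromosome 3 from 52302484 to 52303179 and chromosome 5 from 167911783 to 167912533. With loess the shared count was 1, and the sign-turned ratios of array 1 gave 260 clusters against 17.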

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

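The random-sequence curve and the 2 uncentred settings were chosen after seeing the data, and the cause of each change was not tested unless stated. Tukey centring and the stricter overlap of clusters changed no count by over 1.5 times, and 10 probes per region left both counts of regions the same. All 26 named tiles and regions kept their direction and call with Tukey centring, medians, without dim probes and without repeated probes. With normexp all 26 kept their direction and 6 lost the call. In loess 6 reversed, 17 lost the call and 3 were kept. Each array alone lies within 1 SD of the mean of both by construction, so it says nothing about stability.

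Tiles called higher (16290) and lower (7626) were 612 and 1444 with normexp, 4 and 33 with loess, 5 and 41 in the value table, 10147 and 4562 with 1000 bp tiles, and 1700 and 19 with limma treat. They were 1 and 15 with the random-sequence curve, 0 and 16 with loess over all probes without centring, and 7 and 32 in the uncentred value table. Unadjusted p under 0.05 held for 6041 tiles with loess, 5928 with the random-sequence curve and 5839 with uncentred loess. Tiles of 250 bp gave 24532 higher, from more tiles, and adjusted p under 0.01 gave 3731 lower.

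Regions called higher (318) and lower (92) were 54 and 59 with normexp, 0 and 14 with loess, 0 and 11 in the value table and 0 and 0 with the random-sequence curve, where 27, 33 and 22 in the last 3 had an unadjusted p under 0.05. With medians they were 216 and 225, so the excess of higher regions was lost. Lower regions were 45 without dim probes.

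Tiles at 1 or more (879) and at -1 or less (2) in both arrays were 37 and 84 with normexp, 1 and 22 with loess, 2 and 10 in the value table, 1486 and 10 without dim probes, 2941 and 21 with 250 bp tiles, 212 and 1 with 1000 bp tiles and 1 and 22 with the random-sequence curve. They were 45 and 0 at a cutoff of 1.5, and 7969 and 1674 at 0.5. Low tiles were 6 with medians and 0 with at least 5 probes. One array alone gave 1698 to 2122 high and 145 to 187 low tiles.

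The correlation of tiles between arrays (0.79) was 0.40 with normexp, 0.28 with loess, 0.27 in the value table, 0.73 with medians and 0.26 with the random-sequence curve.

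Clusters in array 1, array 2 and both were 13, 2 and 2. With normexp array 2 and the shared count were 0 and 0, with 48 sign-turned in array 1. With loess they were 1 and 1, with 260 sign-turned, and with the random-sequence curve 1 and 1, with 282. Without dim probes they were 24, 1 and 1, with 0 sign-turned. Without repeated probes there were 0 sign-turned. With 1000 bp windows array 1 had 4 and 1 was shared, with 0 sign-turned. At 1% of permuted windows they were 7, 1 and 1, with 0 sign-turned. In the value table they were 4924, 5304 and 2020, and sign-turned 2590, 5584 and 991. Permuted positions are no fair background for values smoothed along the genome. One array alone gave 2 to 13.

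These values reversed. The unnamed housekeeping control was -0.25 with loess, -0.17 in the value table and -0.34 with the random-sequence curve. GAPDH was -0.24, -0.10 and -0.30 in that order, the piRNA region on chromosome 1 -0.23, -0.14 and -0.28, the piRNA region on chromosome 15 -0.10, -0.045 and -0.15, and the chromosome 22 tile from 31485500 -0.065, -0.13 and -0.26. The chromosome 11 tile from 1910500 was -0.015 with loess and -0.19 with the random-sequence curve. Both tiles hold saturated probes and had loess SEs of 0.12 and 0.11, so no direction is read from them. With that curve the miRNA regions on chromosomes 8 and 20 were -0.023 and -0.021, above the median region at -0.079, so these signs follow a common shift. The values of the housekeeping and piRNA regions with that curve include this shift too.

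Not run were the GC correction, the miRNA lists under any setting, and each array alone for the tile and region tests and the correlation, which leave no residual degrees of freedom or nothing to correlate. No paired analysis was possible because the design has 1 group. Only 10.2% to 12.8% of genomic probes exceeded the 95th percentile of random-sequence probes, by channel and array, which limits what these arrays can show.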

Other observations

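The tests chosen after the result was seen were the brightness trend, the scanner background, the array surface and the flanks and direction of the stretches, and every count of stretches, whose limit of 200 bp between neighbours was added after a first count. The tests of single probes and of fragments over all probes were set before their values were seen.

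With loess, 14 regions were called lower: 6 of 12 housekeeping transcripts, 7 of 79 piRNA regions and 1 of 297 miRNA regions. Enrichment by class was not tested. These calls used 1 SE of 0.054 for every region, whatever its number of probes. RPLP0, a ribosomal protein, had loess means of -0.76 in array 1 and -0.13 in array 2, and HSP90AB1, a chaperone, had -0.49 and -0.15. ACTB had -0.54 and 0.02, so it was below 0 in 1 array only. The miRNA region was on chromosome 2 from 132721971 to 132746971, at -0.38 (limma adjusted p = 8.13e-10). Relative to the random-sequence probe curve none of the 552 regions was called by limma, with 22 at an unadjusted p under 0.05.

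Runs of at least 3 neighbouring probes with a loess ratio beyond 1 in size in both arrays numbered 5 above and 17 below, against a mean of 0.02 for each with permuted positions. Permuting positions removes any likeness of neighbouring probes, whatever its source, so this excess does not single out bound sites. The 5 above were the chromosome 22 site at 31716052 to 31716207, snoRNA regions on chromosome 9 at 133343484 to 133343629 and chromosome 19 at 17832758 to 17832908, a piRNA region on chromosome 15 at 98130409 to 98130509 and a miRNA region on chromosome 11 at 72017419 to 72017519. The chromosome 9 run had 4 probes, with means of 2.85 and 1.86. The lowest of the 17, in a miRNA region on chromosome 1 at 1078350 to 1078750, had means of -3.23 and -2.44. Its mean input brightness was 40741 against 4051 for ChIP in array 1.

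The first pattern is the large number of tiles called higher in the main setting. Relative to random-sequence probes of the same brightness, the median ratio of these 16290 tiles was 0.02, against 0.60 in the main setting, or 2.78% of it; over the median of all tiles it was 0.09 against 0.50, or 17.3%. A brightness trend that random-sequence probes share may therefore account for much of the ratio of these tiles, by a share that stays unknown. Brightness here includes the ChIP channel, so real enrichment also makes a probe brighter. The comparison, like loess, would then remove part of a real gain too. After normexp, 3.66% of the 16290 tiles were still called, but their median ratio was 0.30 and the median SE rose from 0.14 to 0.23, so both a smaller ratio and a wider spread ended calls. Whether unequal scanner background underlies the trend stays open, and no biological explanation was tested because the design has 1 group.

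The second pattern is the short stretches. A defect on the array surface is argued against: neighbouring probes of a stretch lay apart by 115% of the distance between random pairs. Fragments around a bound site, which raises ChIP over input, stay open for the 5 stretches above. The 17 stretches below were picked by their loess sign. In the main setting all 17 were below 0 in array 1. Low loess ratios favour low main ratios, so the way the stretches were picked bears on this result. In array 2, 8 of the 17 were above 0, by at most 0.37. Neither array therefore settles whether a bound site underlies them. For the 5 above, probes within 200 bp outside kept a median of 9.91% of the ratio. For the 17 below that median was 41.9%, with quartiles of 15.1% and 69.3%. However, ending a run at a probe short of the cutoff weakens flanks by an unknown amount. Some of the 17 lie side by side in the same region, so they are not all separate sites. Sequence that differs in amplification between ChIP and input stays open and untested.

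The third pattern is the part of the ratio that repeats between arrays after loess. Random-sequence probes repeated with 87.5% of the correlation of genomic probes (0.24 against 0.27), which suggests effects of single probes, such as sequence and cross-hybridization, as a candidate explanation. The correlation of a probe with its next neighbour in the other array was 0.04, or 13.1% of that with the same probe, which argues against DNA fragments as the main source of the repeat. A small set of sites with real fragments is not excluded by these values over all probes.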
